A study of Homo sapiens with 166 samples.

How the data were processed

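Polyadenylated RNA from sorted blood cells was sequenced with the Smart-seq2 protocol in 166 libraries. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.13 and reads were quantified with kallisto 0.43.0 against hg19. The deposited table holds estimated counts per gene and library without normalization by the authors. The notes do not state how transcripts were summed to genes. Only 0.07% of nonzero values were whole, and all values were rounded before fitting. The table had 20206 genes under Ensembl gene identifiers. XIST, TSIX and Y-linked genes (48) were left out, which left 20158. Symbols came from a table of current gene names (19492 identifiers) and GENCODE v29 (64), which left 650 with 0.23% of the counts unnamed, and GC content came from GENCODE v29 on GRCh38.

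Libraries carry no molecular identifiers, and floors cover counting error only. Samples were grouped by cell type and treatment as labelled, and donors were numbered as replicates. Groups with 1 or 2 libraries were described and not tested. Among 13695 pairs of libraries 0 were identical, and the highest correlation of log2 CPM was 0.992. The lineage of each library was checked against marker lists, and 8 of 166 did not have the labelled lineage as the highest.

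Each comparison was fitted alone in edgeR 4.0.16 under R 4.3.3 with TMM scaling, filterByExpr and the robust quasi-likelihood test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. This test, the comparisons, the gene lists and the rule for named genes were fixed before the data were examined. The 30 comparisons were 18 stimulations, 9 pairs of cell types, 1 pair of LPS protocols and 2 interactions. Errors of log2 changes are standard errors from the fit, and CPM values are group means with the SD between libraries. Those of named genes carry the scaling of 1 comparison and are not comparable between comparisons. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where they had 1 to 3 counts, the counts are given instead of a fold. Log2 CPM values in the list tests and donor averages used a prior count of 2, while edgeR's fitted log2 changes used that package's default.

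Named genes were, for each main comparison, the 6 largest rises and 6 largest falls among called genes with no overlap between the libraries of both groups and a mean of at least 10 CPM in the higher group. Up to 4 called members of each list assigned to the comparison and a fixed set of genes reported whatever their result were added. In the donor-averaged T cells and the groups with few libraries, the named genes were chosen after their values were seen.

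Gene lists (36, with 560 members of which 548 were in the table) were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation of 0.01 and with an estimated correlation. Adjustment covered all 989 list tests, which put the unadjusted p at the threshold at 0.0148. Camera compares the genes of a list with other genes. Counts adjusted over the list alone applied the Benjamini-Hochberg method to the members of 1 list.

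Libraries with the same replicate number come from the same donor and are paired. Over 29 comparisons the 136 same-donor pairs had a median correlation of deviations from the group means of 0.25 (from -0.13 to 0.68) across genes, against -0.10 for other pairs, and 120 of the 136 exceeded 0.1. GC bias was measured as the Spearman correlation across genes between a library's relative log2(CPM + 1) and GC content, over 6133 genes in 147 libraries for the shares of variance. The GC correction fitted a smoothing spline with 6 degrees of freedom to the trimmed means of 40 bins of GC content per library and entered the result as offsets. Donor averages took the log2 CPM difference of each same-donor pair of libraries, averaged it over related cell types within each donor and tested the mean over donors with limma's robust moderated test with a trend.

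The pipeline was tested on simulated data shaped like Naive_Teffs with 200 changed genes. At a set dispersion of 0.1 edgeR made 153 calls with 0 false and recovered 8%, 98%, 100% and 100% of 2-, 4-, 8- and 16-fold changes. With the block it made 165 calls with 3.6% false, DESeq2 had 1.3% false and limma voom with the block 4.2%. At the dispersion of the real libraries edgeR and limma voom with the block made 1 call each, the edgeR block 3 and DESeq2 100, of which 62% were false. The donor-averaged test at the real dispersion made 101 calls with 0% false and recovered 0%, 18%, 84% and 100%. Simulated donors shared each gene's fold and had a donor effect of SD 0.2 (natural log). These rates may not hold for the real calls. The changed list was called, and 0 of 20 unchanged lists were.

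Alternatives set beforehand were RLE scaling, no filter on low counts, a filter of at least 5 CPM, DESeq2 1.42.0, a replicate block, a minimum change of 2-fold, all groups in 1 fit, an estimated correlation for lists, another pseudocount for the lineage check, and leaving out each library. The others, among them leaving out 11 libraries of low depth or unmatched lineage, and the 5 donor-averaged analyses were added after the data were seen.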

Results

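RNA was sequenced with Smart-seq2 in 166 libraries of 25 immune cell types from the blood of 8 healthy donors, numbered here as replicates 1 to 8. Untreated cells gave 83 libraries, treatment 1 gave 71 and treatment 2 gave 12. These formed 50 groups of 1 cell type and 1 treatment: 32 groups of 4 libraries, 7 of 3, 6 of 2 and 5 with a single library. Treatment 1 lasted 24 h. T cells received CD3/CD28 beads with IL-2 at 50 U/ml (300 U/ml for regulatory T cells), and B cells received 10 µg/ml anti-IgG/IgM with 20 ng/ml IL-4. Monocytes received lipopolysaccharide (LPS) at 1 µg/ml, and NK cells received IL-2 at 200 U/ml. Treatment 2 was LPS at 100 ng/ml for 6 h in monocytes and 48 h of receptor beads with 500 U/ml IL-2 in NK cells. The labels did not describe it for naive B cells, Naive_Teffs or Naive_Tregs. Total estimated counts per library ran from 0.97 M to 71.83 M (mega counts) with a median of 28.2 M.

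In the untreated libraries the mean log2 CPM (counts scaled to the library total) of the T cell markers was 6.86 ± 1.32 (SD, n = 56) in T cells. The B cell markers stood at 6.53 ± 1.88 (SD, n = 12) in B cells, and the NK markers at 5.95 ± 0.95 (SD, n = 6) in NK cells, where the T cell markers were at 4.16 ± 0.67. Monocyte markers reached 9.66 ± 0.97 (SD, n = 4) in monocytes and 6.45 ± 2.1 (SD, n = 3) in myeloid dendritic cells, whose dendritic cell markers were at 5.08 ± 1.78. The B cell libraries also carried monocyte markers at 3.04 and plasma cell markers at 4.39 on average. The highest of the lineage lists matched the label in 81 of the 83 untreated libraries and in 158 of all 166.

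GC content separated donors more than cell types. Within each library, the Spearman correlation across genes between relative expression and gene GC content had a median of 0.46 in replicate 1 (n = 42), 0.12 in replicate 2 (n = 35), -0.28 in replicate 3 (n = 36) and -0.06 in replicate 4 (n = 34). Medians of replicates 5 to 8 lay between -0.34 and -0.24. Across 147 libraries of replicates 1 to 4, donor accounted for 90.6% of the variance of this correlation, cell type for 4.5% and treatment for 1.5%. The tests below were fixed without a donor term, and values with a donor term (block) are given where they change a call or move a count by more than 1.5 times.

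**Figure D1:**
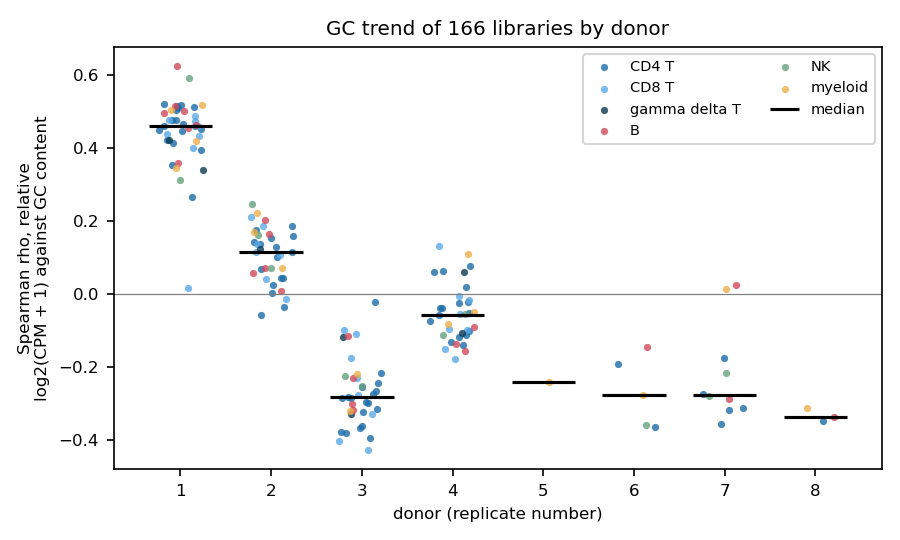
Spearman correlation across genes of relative log2(CPM + 1) with gene GC content (y axis, no unit) in each of the 166 libraries by donor replicate (x axis), coloured by lineage, with black bars at the medians. Medians ran from 0.46 in replicate 1 to -0.34 among replicates 5 to 8.

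Naive CD4 effector T cells (Naive_Teffs) were stimulated with CD3/CD28 beads for 24 h. IL2, the growth factor that activated T cells secrete, rose from 0.256 ± 0.196 to 562 ± 626 CPM (SD, n = 4 each), and its receptor chain IL2RA rose from 4.63 ± 4.54 to 456 ± 78.3 CPM. Cell cycle entry showed in the replication origin genes CDC6 (log2 change 8.55 ± 1.46, SE), MCM10 (7.65) and GINS2 (7.32) and in thymidylate synthase TYMS (7.12). The cell cycle genes UBE2C and CDC25A were at 0 in all untreated libraries and at least 713.5-fold and 557.6-fold higher after stimulation, over a floor of 3 counts for the group. DTL stood at 112 ± 76 CPM after stimulation against 1 count in the 4 untreated libraries, CDK1 at 45 CPM against 1 count and CDC20 at 69.7 CPM against 2 counts. Genes of the resting state fell: the homing regulator KLF2 from 87.6 to 0.0878 CPM (-9.97 ± 1.64), the PI3K inhibitor PIK3IP1 (-6.78 ± 0.9), the glucose uptake inhibitor TXNIP (-4.94 ± 0.78) and KLF3 (-5.12). The immediate early gene FOS fell from 906 to 1.33 CPM (-9.51 ± 1.06, edgeR adjusted p = 0.00254), and the glucose transporter SLC2A3 fell from 488 to 46 CPM. Other rises were the cytokine TNFSF14 (8.21 ± 1.17), the ribosome biogenesis genes NOLC1 (4.21 ± 0.94) and MRTO4 (5.04 ± 1.15) and NUSAP1 (6.04, adjusted p = 0.0536 with the block). LIF (439.9-fold), PHEX (577.6-fold), SLC27A2 (564.7-fold) and RPP25 (469.4-fold) were higher by at least these values over 0 counts at rest. TCP11L2 (-9.61), CCDC65 (-9.7) and FSBP (-9.08, 0.0566 with the block) fell as well, and HAVCR1 was left with 3 counts after stimulation. IFNG (4.86, adjusted p = 0.127), MKI67 (2.61, 0.455), MYC (0.86, 0.719) and CD69 (-1.18, 0.382) did not pass, nor did CCR7 (-1.82, 0.361), which passed with the block (0.0254).

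Across 11405 tested genes in Naive_Teffs, edgeR called 317 (188 higher, 129 lower), the block raised this to 582 (356 higher, 226 lower) and the GC correction gave 511 (212 higher, 299 lower). The cytokine list rose with 3 of 9 measured members passing (7 adjusted over the list alone), a median log2 change of 4.87 and a camera adjusted p of 5.19e-07, which became 0.069 with an estimated correlation. DNA replication genes rose with 7 of 24 (15 over the list alone, median 3.37, 6.26e-12, 0.0694 estimated), and mitosis genes with 4 of 20 (13, median 4.85, 2.50e-10, 0.0694 estimated). MYC and ribosome biogenesis genes rose with 2 of 21 (8, median 2.41, 3.04e-06, 0.158 estimated) and activation receptors with 1 of 12 (4, median 1.74, 0.00913, 0.208 estimated). Quiescence and homing genes fell with 8 of 16 (12, median -3.19, 3.50e-09, 0.171 estimated). For glycolysis no member of 16 rose and 1 fell (6 and 1 over the list alone), while the list passed upward (median 2.08, 0.0153, 0.578 estimated). Cholesterol synthesis (19 genes, 0 passing, 2 over the list alone, median 1.21, 0.182), interferon-stimulated (22, median -1.38, 0.0655) and MHC class II genes (10, median -0.3, 0.225) did not pass. The count of 317 became 74, 3 or 17 without treated replicate 1, 2 or 4, and 23, 85 or 153 without untreated replicate 2, 3 or 4. Of the 29 named genes that passed, FOS kept its call whichever library was left out and 28 lost it at least once. The receptor list lost its call without both libraries of replicate 1 (unadjusted p = 0.0184 against a limit of 0.0148).

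Naive CD8 T cells (Naive_CD8_T) received the same stimulus. IL2RA rose from 1.15 to 1003 ± 85.8 CPM (log2 change 9.73 ± 1.35, edgeR adjusted p = 0.0123), and the costimulatory receptors TNFRSF4 (10.63 ± 1.99), TNFRSF9 (8.77) and TNFRSF18 (9.09, adjusted p = 0.0593 with the block) rose with it. The cytokine CSF2 rose from 0.105 to 108 CPM (10.02 ± 1.71) and TNFSF14 by 8 ± 1.26. Of the cell cycle genes, GINS2 (10.56 ± 1.38, 0.00806), CDC20 (11.11 ± 1.78), CDK1 (9.02), CDC6 (8.79), RRM2 (9.3, 0.0526 with the block) and MCM10 (6.16, 0.0652 with the block) rose. CCNB1 reached 41.6 CPM against 2 counts at rest, CCNB2 6.51 CPM against 1, BYSL 44 CPM against 1 and ECE2 30.1 CPM against 1. Genes at 0 counts at rest were higher by at least 533.6-fold (LIF), 640.4-fold (RPP25), 522.6-fold (TTK), 426.8-fold (SPR) and 134.2-fold (CXCL10). With the block their adjusted p values were 0.0593, 0.0594, 0.0592, 0.0623 and 0.0701. The immediate early genes FOS (938 to 3.19 CPM, -8.23 ± 0.89, 0.00268), DUSP1 (2466 to 9.22 CPM, -8.09 ± 1.03) and FOSB (-7.75) fell. So did KLF2 (-10.49 ± 1.71), PIK3IP1 (-5.99 ± 0.88), TXNIP (-4.16), KLF3 (-4.49, 0.0767 with the block), RBM43 (-9.14, 0.0623 with the block) and H2BC4 (-9.19, 0.129 with the block). The cytotoxic genes gave no call: GZMB was at 2095 against 335 CPM (2.6, 0.418) and PRF1 changed by -0.07. IFNG (2.43), MYC (1.97), MKI67 (0.39) and CD69 (-1.96, 0.212) did not pass either.

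In Naive_CD8_T edgeR called 143 of 11978 genes (101 higher, 42 lower), the block gave 100 (50 higher, 50 lower) and the GC correction 571 (189 higher, 382 lower). Activation receptors rose with 4 of 12 members (5 higher and 1 lower adjusted over the list alone, median 3.25, camera adjusted p = 6.39e-04, 0.226 with an estimated correlation). Cytokines rose with 3 of 9 (7, median 4.95, 1.75e-06, 0.261 estimated), DNA replication genes with 4 of 25 (12, median 3.9, 1.07e-12, 0.207 estimated) and mitosis genes with 4 of 18 (9, median 2.98, 4.07e-08, 0.121 estimated). MYC and ribosome biogenesis genes rose with 1 of 21 (2, median 2.48, 3.43e-05, 0.264 estimated). Quiescence genes fell with 5 of 16 (10, median -2.38, 4.62e-09, 0.151 estimated). Glycolysis passed upward with 0 of 16 members (4 higher and 1 lower over the list alone, median 2.03, 0.0311, 0.668 estimated). The cytotoxic granule list passed downward with 0 of 13 members (median -2.27, 0.0495, 0.729 estimated), while the mean log2 CPM of NK markers ran from 0.08 to 3.97 in the untreated and 0.66 to 3.53 in the treated libraries. Cholesterol (median 0.38, 0.222) and MHC class II genes (median -2.15, 0.11) did not pass. For 23 interferon-stimulated genes (1 rose) the median was -0.33, the mean 0.13 and the test pointed down (0.967). The count of 143 became 4, 0, 4 or 1 without treated replicate 1, 2, 3 or 4, and 29, 20 or 78 without untreated replicate 1, 2 or 4, and all 30 named genes that passed lost their call at least once. Glycolysis lost its call without treated replicate 1 (unadjusted p = 0.0166) or 2 (0.0178), or without both libraries of replicate 1 (0.0225) or 2 (0.0149). The cytotoxic list lost it without treated replicate 3 (0.0691) or 4 (0.0333) or untreated replicate 1 (0.0423), 2 (0.16) or 4 (0.0159).

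Regulatory T cells (Regulatory_T, 3 treated and 4 untreated libraries) were stimulated in turn. IL1R2, the decoy receptor for IL-1, rose from 0.0328 CPM (4 counts) to 187 ± 80 CPM (log2 change 12.24 ± 1.37, edgeR adjusted p = 0.00405). ZBED2 stood at 123 ± 60 CPM against 3 counts in the untreated libraries (adjusted p = 0.0213). IL2RA was at 2685 against 280.5 CPM (3.28, 0.119, and 0.0368 with the block), and the suppressive cytokine IL10 was at 83.8 against 0.289 CPM (8.18, 0.119). CTLA4 (1.97, 0.376), the lineage factors FOXP3 (0.65) and IKZF2 (0.62), IL2 (4.49) and MKI67 (-5.08) did not pass. These were the only calls among 11951 genes by edgeR, which found 950 genes at an unadjusted p under 0.05. DESeq2 called 324, and the block called 41 (9 higher, 32 lower). No member of the following lists passed alone. Cytokines rose as a list (12 genes, 6 adjusted over the list alone, median 4.8, camera adjusted p = 3.88e-15, 0.0616 with an estimated correlation), as did activation receptors (14 genes, 5 higher and 1 lower over the list alone, median 2.52, 1.58e-04, 0.261 estimated). Regulatory T cell genes rose (17 genes, 1 over the list alone, median 1.65, 1.14e-04, 0.358 estimated), and quiescence genes fell (16 genes, 5, median -1.62, 1.47e-05, 0.172 estimated). MYC targets (median 0.51, 0.00948, 0.228 estimated) and glycolysis (median 1.37, 0.0171, 0.482 estimated) passed upward. DNA replication (0.12, 0.128), mitosis (-0.2, 0.771), interferon-stimulated (-0.92, 0.174) and MHC class II genes (-1.27, 0.131) did not pass by median and adjusted p. Cholesterol genes (1.32, 0.184) passed with the block (0.0232). The count of 2 became 0 without treated replicate 1, and 1 without treated replicate 2 or 3 or untreated replicate 1, 2 or 4. The MYC list lost its call without treated replicate 1 (unadjusted p = 0.0235) or 3 (0.0175), and glycolysis without treated replicate 1 (0.0276).

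B cells received anti-IgG/IgM with IL-4. In bulk B cells (Bulk_B, 3 treated and 4 untreated libraries) the IL-4 response list rose with a median log2 change of 5.1 over 10 genes (0 passing over all genes, 6 adjusted over the list alone, camera adjusted p = 4.35e-07, 0.158 with an estimated correlation). B cell activation genes rose (18 genes, 5 higher and 1 lower over the list alone, median 2.53, 4.01e-04, 0.199 estimated). Cholesterol synthesis (19 genes, median 1.93, 4.66e-04, 0.172 estimated) and MYC targets (median 0.89, 0.00834, 0.244 estimated) rose. MHC class II genes fell (median -1.82, 0.00422, 0.431 estimated), and the mean log2 CPM of monocyte markers was 1.33 (0.72 to 1.83) against 2.99 (1.49 to 4.49) and of B cell markers 5.3 against 6.41. Single genes gave CPM means of 48.4 ± 20 against 6.83 ± 9.07 for the costimulator CD86 (edgeR adjusted p = 0.584), 455 against 139 for CD83 (0.755), 1791 against 868 for the IgE receptor FCER2 (0.964) and 39.2 against 25.1 for MYC. CD69 was at 81.7 ± 21.8 against 1117 ± 430 CPM (0.453), MKI67 was below the filter at 1.18 against 1.53 CPM, and CCL3 and CCL4 matched no named identifier. The unfolded protein response list missed the threshold (0.75, 0.0505) and passed with the block (0.0314). DNA replication (0.31, 0.125) and glycolysis (0.73, 0.256) did not pass. Mitosis had a median of -0.1, a mean of 0.11 and an upward test (0.793), and plasma cell genes a median of -0.94, a mean of -0.29 and an upward test (0.735). EdgeR called 0 of 11690 genes, with 1100 at an unadjusted p under 0.05. DESeq2 called 343, the block 9 (4 higher, 5 lower), limma voom with the block 49 and a fit of all groups together 139. The count of 0 became 1 without treated replicate 1 or 2 or untreated replicate 1, 2 or 3, and 3 without treated replicate 3. The MHC class II list lost its call without treated replicate 3 (unadjusted p = 0.0154). Memory B cells (Mem_B) had 36 calls (11 higher, 25 lower), 76 with the block (46 higher, 30 lower), 44 with the GC correction (25 higher, 19 lower), and 10, 6 or 4 without treated replicate 1, 2 or 3 and 7, 7 or 2 without untreated replicate 1, 2 or 7. An analysis of donor averages over B cell types also put the IL-4 list up (8 of 11 over the list alone, median 5.52, 4.16e-06, 0.281 estimated) and B cell activation (6 of 18, median 3, 0.00107, 0.281 estimated), with 0 genes by limma and 780 at an unadjusted p under 0.05.

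Mature NK cells (Mature_NK, 4 treated and 4 untreated libraries) received IL-2 at 200 U/ml. No named gene that was tested passed. IL2RA was at 48 ± 90 against 3.03 ± 2.23 CPM (edgeR adjusted p = 0.773), the granule genes GZMB at 7144 against 10584 and PRF1 at 1676 against 1461, IFNG at 10.2 against 46.2, MKI67 at 5.03 against 10.3 and the Fc receptor FCGR3A at 772 against 531. CISH, an IL-2 target, was below the filter at 13.8 against 0.0875 CPM. Immediate early genes fell as a list (15 genes, 7 adjusted over the list alone, median -2.91, camera adjusted p = 2.20e-08, 0.202 with an estimated correlation). The lists chosen for NK cells did not pass: activation receptors (median 0.76, camera adjusted p = 0.892), DNA replication (0.8, 0.218), mitosis (0.46, 0.586), MYC targets (0.22, 0.997), glycolysis (-0.47, 0.339) and interferon-stimulated genes (0.54, 0.584). Cytokines (1.35, 0.064) and cytotoxic granule genes (-0.77, 0.0871) passed with the block (0.0436 and 0.0448). EdgeR called 0 of 11030 genes with and without the block, with 706 at an unadjusted p under 0.05. DESeq2 called 196, limma voom with the block 15 and the fit of all groups 6, and 1 gene passed without untreated replicate 2.

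Monocytes after 24 h of LPS (1 µg/ml) were compared with untreated ones. Chemokines rose: CCL2 from 0.318 to 5473 CPM (log2 change 13.9 ± 1.82, edgeR adjusted p = 0.00265), CXCL1 (12.59 ± 1.86), CXCL5 (12.56 ± 1.55) and the neutrophil attractant CXCL8 from 317 to 23669 CPM (6.15 ± 1.1). The inflammatory cytokine IL1B rose from 78.3 to 10030 CPM (6.94 ± 1.42, 0.0273) and the anti-inflammatory IL10 from 1.25 to 113 CPM (6.42 ± 1.12). IDO1 reached 974 ± 1102 CPM against 1 count in the 4 untreated libraries. Genes at 0 counts at rest were at least 15672-fold (MUCL1), 14050-fold (IL1A), 11825-fold (WNT5A), 9419-fold (CXCL6), 8653-fold (IL36G) and 1359-fold (EBI3) higher. Antigen presentation fell: CD74, the invariant chain, from 21507 to 363 CPM (-5.89 ± 1), HLA-DPB1 (-7 ± 0.86), HLA-DPA1 (-6.06) and HLA-DMB (-5.97). The lectin FCN1 fell from 4335 to 3.6 CPM (-10.2 ± 2.11), with LGALS2 (-8.94) and FCER1A (-8.45), and TNNI2 was left with 3 counts. MT1F rose (5.26, 0.0495, and 0.112 with the block). At 0 counts after LPS, TAMALIN was at least 391.3-fold and TNFSF12-TNFSF13 at least 436.1-fold lower (0.0642 and 0.0578 with the block). IL6 stood at 1118 ± 2022 against 2.88 CPM (8.52, 0.103) and CD14 changed by 2.06 (0.414), and both passed with the block (0.00621 and 0.0352). TNF (0.4) and CIITA (-2.06) did not pass.

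Of 11678 genes in LPS-treated monocytes, edgeR called 193 (142 higher, 51 lower), and the block called 269 (165 higher, 104 lower). NF-kB target genes rose with 11 of 25 members (16 adjusted over the list alone, median 6.03, camera adjusted p = 3.67e-14, 0.0678 with an estimated correlation). Metallothioneins rose with 1 of 4 (3, median 4.5, 0.00313, 0.43 estimated). MHC class II genes fell with 5 of 10 (7, median -5.01, 1.14e-07, 0.171 estimated), and interferon-stimulated genes fell as a list with 0 of 21 (median -1.22, 0.0167, 0.566 estimated). Monocyte markers (13 genes, 1 fell, 1 higher and 4 lower over the list alone, median -0.35, 0.234), glycolysis (0.02, 0.713) and cholesterol genes (0.24, 0.293) did not pass. The mean log2 CPM of dendritic cell markers was 0.61 (0.18 to 1.2) against 2.01 (1.56 to 2.45). The count of 193 became 113 without treated replicate 2, and 78, 40, 115 or 80 without untreated replicate 1, 2, 3 or 4. Of 24 named genes that passed, 13 lost the call at least once, and CCL2, CD74, CXCL1, CXCL5, CXCL6, HLA-DPB1, IDO1, IL1A, IL36G, MUCL1 and WNT5A kept it. The interferon list lost its call without treated replicate 1 (unadjusted p = 0.016) or 3 (0.0159) or untreated replicate 1 (0.0622), and metallothioneins without both libraries of replicate 4 (0.0191).

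The 2 LPS protocols were compared. Treatment 2 (100 ng/ml, 6 h) used replicates 5 to 8 and treatment 1 replicates 1 to 4, so dose, time and donors cannot be told apart. Interferon-stimulated genes were higher under treatment 2 as a list (23 genes, 0 passing over all genes, 11 adjusted over the list alone, median log2 difference 2.99, camera adjusted p = 7.24e-09, 0.358 with an estimated correlation). Monocyte markers had a mean log2 CPM of 5.54 (3.97 to 6.33) under treatment 2 against 8.45 (6.99 to 9.77), and T cell markers 1.65 (0.43 to 3.81) against 1.07 (0.41 to 1.36). IFIT1 was at 1789, 881, 6.86 and 848 CPM under treatment 2 and between 0.775 and 24.9 CPM under treatment 1. Metallothioneins were lower (2 of 4 passing, median -5.28, 1.37e-04, 0.244 estimated), led by MT1X (-8.13, edgeR adjusted p = 0.0463) and MT1F (-7.47). TMEM176B (-9.34, 0.0463), TM4SF1 (-8.97, 0.0497), MUCL1 (-8.45) and CDA (-7.68) were also lower, and SPARC was at 12.9 CPM under treatment 1 against 1 count. The antiviral ZC3HAV1 was at 4775 against 53.9 CPM (6.52) and the survival factor BCL2 at 24.2 against 0.203 CPM (6.9 ± 1.48), with TENM4 (8.81), DNAAF1 (7.51) and ALDH1B1 (6.46) also higher (adjusted p = 0.0497 each). IL6 (-0.44), CCL2 (0.47), IL1B (-0.66), TNF (0.6), CXCL8 (-1.74) and IL10 (-2.1, 0.253) did not pass. NF-kB targets (-0.44, 0.94), cholesterol (-1.26, 0.212) and MHC class II genes (1.43, 0.0897) did not pass as lists. EdgeR called 29 genes (6 higher, 23 lower), with 2479 at an unadjusted p under 0.05, and DESeq2 called 1582. The 29 became 0 without treatment 2 replicate 5, 6 or 7 or treatment 1 replicate 1, and 77 without treatment 2 replicate 8. They became 19, 52 or 7 without treatment 1 replicate 2, 3 or 4, and all 12 named genes that passed lost the call at least once.

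**Figure D2:**
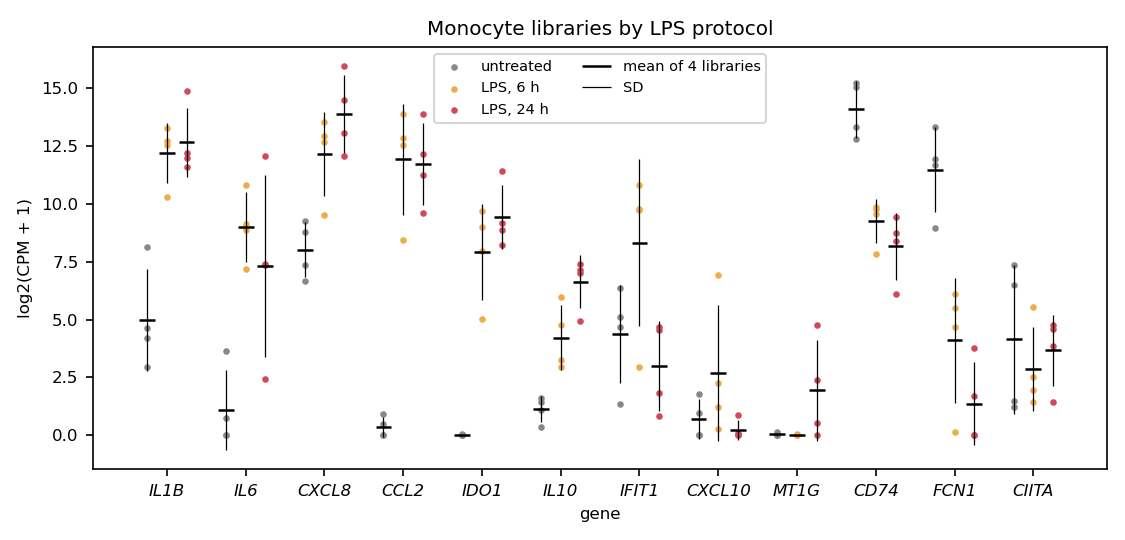
Expression as log2(CPM + 1) (y axis) of 12 genes in each monocyte library (points) that was untreated, under LPS for 6 h or under LPS for 24 h (4 libraries each), with bars at the means. IL1B and CCL2 stood above all untreated libraries after 24 h, and CD74 and FCN1 below.

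The other 12 cell types with 3 or 4 libraries per arm had the same test. Over all 18 stimulation comparisons edgeR called 0 to 586 genes (median 151.5), and 0 to 1007 with the block (median 172.5), which raised the count over 1.5 times in 11 and lowered it as far in 3. CD8 T cells (CD8pos_T) had 545 calls and 1007 with the block. Without treated replicate 2, 3 or 4 they had 119, 229 or 114, and without untreated replicate 1, 2 or 4 they had 218, 314 or 247. Central memory CD8 T cells had 105 (159 with the block, 55 without treated replicate 1). Effector memory CD8 T cells had 87 (327 with the block), 23, 22, 32 or 27 without treated replicates 1 to 4 in turn, and 40 or 46 without untreated replicate 2 or 4. Gamma delta T cells had 22 (11 higher, 11 lower), 93 with the block (29 higher, 64 lower), and 11 with relative log scaling (7 higher, 4 lower). Their B cell markers reached 5.79 in a treated library against at most 1.05 at rest. They had 7 or 11 without treated replicate 3 or 4, and 6, 52 or 12 without untreated replicate 2, 3 or 4. Effector CD4 T cells had 324 (81 with the block), 115, 56, 114 or 94 without treated replicates 1 to 4, and 908, 503 or 197 without untreated replicate 1, 3 or 7. Follicular helper T cells had 459 (899 with the block), 201, 94, 249 or 107 without treated replicates 1 to 4, and 199, 147 or 84 without untreated replicate 1, 2 or 4. Memory_Teffs had 184 (355 with the block), 69, 40, 306 or 36 without treated replicates 1 to 4 and 77, 62, 85 or 71 without untreated replicates 1 to 4. Memory_Tregs had 8 (2 higher, 6 lower), 120 with the block (54 higher, 66 lower), 0, 4, 0 or 0 without treated replicates 1 to 4 and 70, 0 or 0 without untreated replicate 1, 3 or 4. Th1 precursors had 439 (223 higher, 216 lower), 209 with the block (79 higher, 130 lower), 168, 148, 167 or 181 without treated replicates 1 to 4, and 263, 998 or 256 without untreated replicate 2, 3 or 7. Th17 precursors had 160 (103 higher, 57 lower), 186 with the block (69 higher, 117 lower), 93, 44, 58 or 41 without treated replicates 1 to 4 and 59 or 33 without untreated replicate 2 or 7. Th2 precursors had 586 (196 with the block), 105, 84, 182 or 87 without treated replicates 1 to 4 and 326 or 370 without untreated replicate 2 or 7. With the GC correction the counts were 771 in CD8 (384 higher, 387 lower), 324 in central memory CD8 (80 and 244), 340 in effector memory CD8 (94 and 246), 98 in gamma delta (31 and 67) and 1193 in effector CD4 T cells (300 and 893), 96 in Memory_Tregs and 1032 in Th2 precursors.

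**Figure D3:**
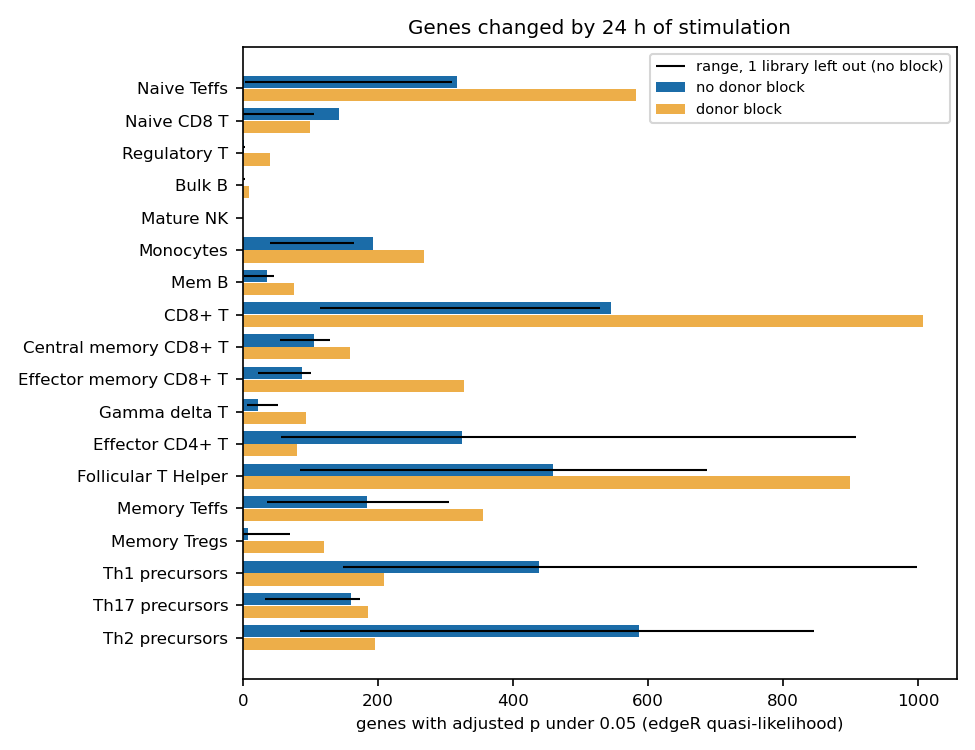
Number of genes with an edgeR adjusted p under 0.05 (x axis) after treatment 1 in 18 cell types (y axis), without a donor block (blue) and with one (yellow), and black lines from the lowest to the highest count when 1 library was left out. Counts without the block ran from 0 in Bulk_B and Mature_NK to 586 in Th2 precursors.

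Gene lists were set side by side over the 14 T cell comparisons. Activation receptors rose in all 14 (medians 1.74 to 3.96), cytokines in 14 (2.62 to 11.57), regulatory T cell genes in 14 (1.15 to 3.78) and MYC targets in 14 (0.51 to 2.48, and 13 with the block). Quiescence and homing genes fell in 14 (medians -3.19 to -1.41). DNA replication genes rose in 12 and mitosis genes in 11. Immediate early genes fell in 11 (12 with the block), naive T cell genes in 10 (11 with the block), mitochondrially encoded genes in 9 (10), interferon-stimulated genes in 6 (7) and monocyte markers in 4. Glycolysis rose in 8 (9), the B cell activation list in 8 (7) and the IL-4 list in 6 (5). NF-kB targets rose in 1 of 18 comparisons, that of monocytes. Of 989 list tests camera called 295 with its preset correlation of 0.01 (304 with the block) and 4 with an estimated correlation. One of the 4 was the cytokine list in stimulated Memory_Teffs, where 17 of 18 members rose with a median of 11.57 (camera adjusted p = 1.23e-28, 0.0157 estimated). This median can depend on the prior count, as members such as IL17A had 0 counts at rest.

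**Figure D4:**
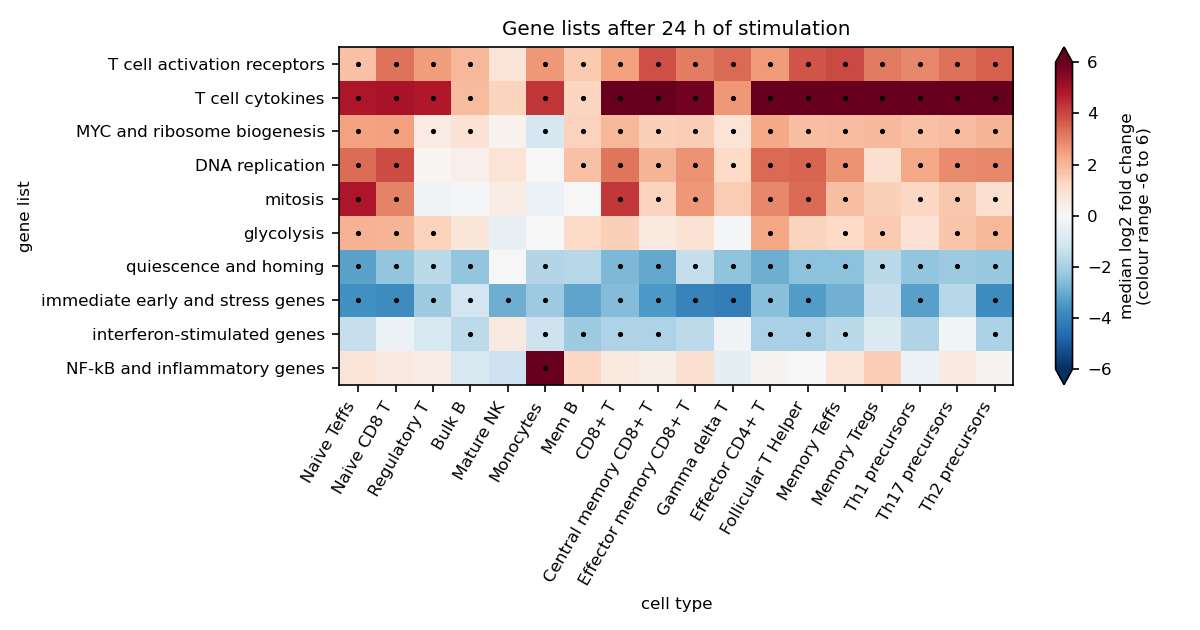
Median log2 fold change (colour, from -6 to 6) of the gene lists (y axis) after treatment 1 in 18 cell types (x axis), with dots where camera's adjusted p at the preset correlation was under 0.05. The cytokine list was above 0 and the quiescence list below 0 in all 14 T cell comparisons.

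The response was averaged over 15 T cell types within each of 4 donors (49 pairs of libraries). CSF2 rose from 0.546 to 551 CPM (log2 change 9.71 ± 0.72, in 48 of 49 pairs, limma adjusted p = 1.45e-04), and IL2 (8.04 ± 0.74, 2.74e-04) and IL2RA (7.19 ± 0.67) rose in 49 of 49. The transcription factors ZBED2 (9.45 ± 0.67) and IRF4 (7.67 ± 0.68, from 12.4 to 720.5 CPM) rose in 49 pairs, along with the receptor TNFRSF9 (9.27 ± 0.75). The cytotoxic protease GZMB rose from 142 to 6003 CPM (6.97 ± 0.82, 49 pairs). KLF2 (-8.72 ± 0.48), FOS (-8.53 ± 0.46, from 1060 to 3.02 CPM), DUSP1 (-8.29 ± 0.48) and JUN (-7.11 ± 0.42) fell in all 49 pairs (3.12e-05 each). All 14 measured cytokines rose (median 5.93, camera adjusted p = 2.45e-10, 0.247 with an estimated correlation), 24 of 25 DNA replication genes (3.59, 8.66e-10, 0.294 estimated), 13 of 19 mitosis genes (2.92, 9.03e-06, 0.294 estimated) and 17 of 21 MYC targets (2.81, 9.03e-06, 0.434 estimated). Of 14 activation receptors 12 rose and 1 fell (3.67, 1.70e-05, 0.294 estimated), and of 16 glycolysis genes 11 rose and 1 fell (2.01, 0.00658, 0.493 estimated). Regulatory T cell genes rose with 9 of 14 (2.18, 5.62e-04, 0.305 estimated). Quiescence genes fell with 11 of 16 (-2.6, 4.72e-09, 0.218 estimated), mitochondrially encoded genes with 6 of 10 (-1.25, 2.00e-04, 0.493 estimated) and immediate early genes with 11 of 18 while 5 rose (-3, 8.81e-05, 0.305 estimated). Interferon-stimulated genes fell with 7 of 22 while 1 rose (-0.94, 0.00154, 0.599 estimated). Limma called 4310 of 11809 genes (2912 higher, 1398 lower), 2696 without replicate 2 and 1429 without replicate 4. The median of all genes was 0.42, and GC correction moved it to -0.18 with 5666 calls (2415 higher, 3251 lower), so the split by direction depends on that correction.

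**Figure D5:**
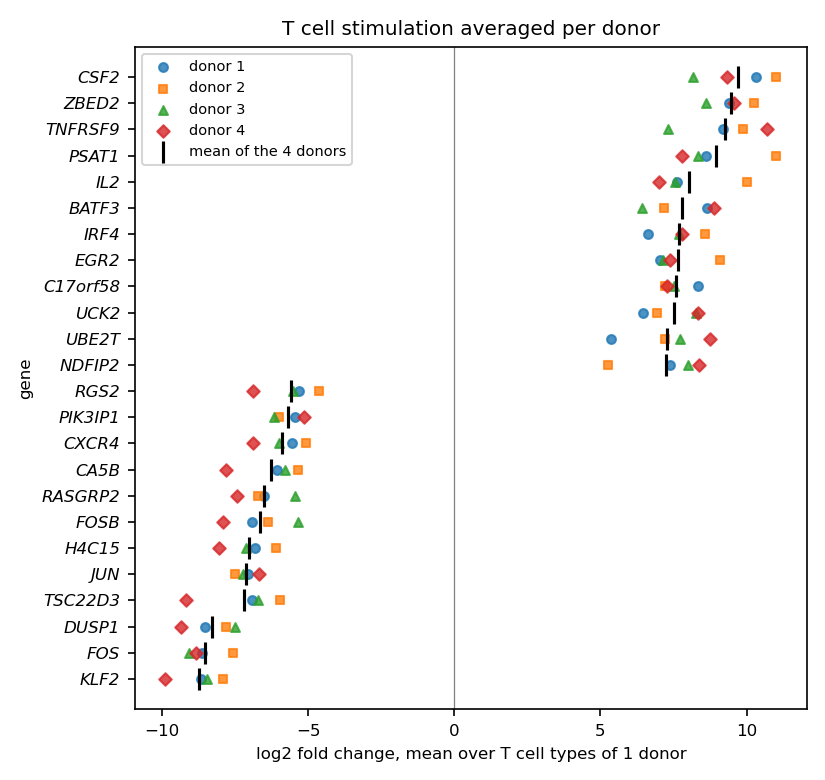
Log2 fold change after stimulation (x axis) of genes (y axis) averaged over T cell types, with 1 marker for each of 4 donors and a mean per gene. All 4 donors were above 0 for IL2 and below 0 for FOS and KLF2.

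Genes shared between cell types were counted. With 0 calls in Bulk_B and Mature_NK, no gene could pass in all 18 comparisons. Of 8809 genes tested in all 18, 285 lay above 0 and 495 below 0 in each. IL2RA was called higher in 13 (median log2 change 6.26, from 1.24 to 9.73) and CSF2 in 12 (10.04, from 3.88 to 12.88). FOS (-8.58, from -10.62 to -5.12), DUSP1, TSC22D3, CXCR4, CNOT1 and CA5B were called lower in 12. Across genes, which are not independent replicates, the Spearman correlation of fold changes had a median of 0.55 between T cell types (91 pairs, 0.39 to 0.76), 0.44 between B and T cells (28 pairs) and 0.19 between monocytes and T cells (14 pairs).

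Memory effector T cells were compared with naive ones at rest (Memory_Teffs against Naive_Teffs). Memory and effector genes were higher as a list (21 genes, 17 adjusted over the list alone, median log2 difference 3.62, camera adjusted p = 5.62e-27, 0.0525 with an estimated correlation). Th17 (10 genes, 5, median 3.43, 1.35e-12, 0.0616 estimated), Th1 (7, 4, 4.24, 6.68e-05, 0.271 estimated), Th2 (5, 2, 1.98, 4.85e-05, 0.15 estimated) and regulatory T cell genes (9 genes, 2.2, 0.0357, 0.315 estimated, and 0.0665 with the block) were also higher. Naive T cell genes were lower (15 genes, 1, -1.06, 4.79e-05, 0.205 estimated). The chemokine receptor CCR6 was at 59.9 ± 33.1 against 0.213 ± 0.0977 CPM (SD, n = 4 each), S100A4 at 640 ± 260.1 against 105 ± 42.9 and TCF7 at 166 against 256. CCR7 was at 281 against 1167 CPM (edgeR adjusted p = 0.999, and 0.0261 with the block), and CXCR3 (4.98 against 0.441) and TBX21 (2.35 against 0.0568) were below the filter. EdgeR called 0 genes, with 376 at an unadjusted p under 0.05, against 78 by DESeq2, 12 with the block and 115 by limma voom with the block. The regulatory list lost its call without Memory_Teffs replicate 2 (unadjusted p = 0.0365) or Naive_Teffs replicate 1 (0.0454) or 2 (0.0384), and the Th1 list without both libraries of replicate 1 (0.0466).

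Effector memory against naive CD8 T cells at rest gave lower naive T cell genes (15 genes, 5 adjusted over the list alone, median -2.93, camera adjusted p = 1.84e-08, 0.0894 with an estimated correlation). Memory genes (23 genes, 3, median 1.21, 5.97e-11, 0.301 estimated) were higher, and cytotoxic genes passed upward with a median of 0.01 (13 genes, 0.00301, 0.574 estimated). NK markers, which varied between the naive libraries (0.08 to 3.97), had a median of -0.29 with an upward test (0.648). The naive factor LEF1 was at 11.7 against 200.5 CPM and CCR7 at 69.2 against 792, while the granzyme GZMK was at 369 against 53.8, EOMES at 52.2 against 11.3 and PRF1 at 100.5 against 37.4. GZMB was at 135 against 288, TBX21 at 6.04 against 4.48 and CX3CR1, below the filter, at 0.0459 against 7.4. EdgeR gave 0 calls (402 at an unadjusted p under 0.05, 78 by DESeq2), and 1 without Naive_CD8_T replicate 2 or 3. The cytotoxic list lost its call without Naive_CD8_T replicate 3 (unadjusted p = 0.0547). Memory against naive B cells had lower naive B genes (12 genes, median -1.94, 1.30e-08, 0.307 estimated) and higher memory B (19 genes, 1.84, 7.56e-07, 0.233 estimated) and plasma cell genes (10 genes, 2, 2.88, 4.04e-06, 0.316 estimated). The memory marker CD27 was at 354 against 3.76 CPM and TNFRSF13B at 144 against 13.3, while the naive markers TCL1A (10.8 against 328), IL4R (16.7 against 144) and FCER2 (75.6 against 544) ran the other way, and CD80 was at 9.48 against 9.34. EdgeR called 0 genes here too (315 at an unadjusted p under 0.05, 35 by DESeq2).

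Regulatory and effector CD4 T cells were compared at rest and stimulated, where IL-2 (300 against 50 U/ml) differed with lineage. At rest the regulatory T cell list was higher (14 genes, 3 adjusted over the list alone, median log2 difference 3.14, camera adjusted p = 7.92e-09, 0.288 with an estimated correlation). FOXP3 was at 28.2 against 0.592 CPM, IKZF2 at 52.4 against 0.226, CTLA4 at 259 against 7.28, IL2RA at 254 against 13.8, CD40LG at 1.97 against 30.9 and IL7R at 224 against 402. Activation receptors were higher (11 genes, 2, 1.85, 0.0108, 0.568 estimated, and 0.106 with the block), and cytokines (-0.89, 0.133) and interferon-stimulated genes (1.08, 0.0894) did not pass. The edgeR test called 0 genes (382 at an unadjusted p under 0.05, 20 by DESeq2, 5 by limma voom with the block), and 13, 19 or 1 without Effector_CD4pos_T replicate 1, 3 or 7 and 2 without Regulatory_T replicate 4. The receptor list lost its call without Effector_CD4pos_T replicate 7 (unadjusted p = 0.0288). After stimulation the list was higher (17 genes, 15 over the list alone, 3.86, 1.79e-21, 0.058 estimated), and cytokines (17 genes, 9, -2.34, 1.19e-09, 0.174 estimated), DNA replication (25 genes, 6, -1.87, 5.36e-12, 0.208 estimated) and mitosis genes (-1.13, 0.00929, 0.507 estimated) were lower. FOXP3 was at 54.9 against 0.78 CPM, IL2 at 21.8 against 875, IL2RA at 3057 against 1045 and CD40LG at 29.9 against 146, and with the block FOXP3 (0.03), IKZF2 (0.0425), CTLA4 (0.0452) and IL2 (0.0164) passed. Receptors were higher (14 genes, 4 higher and 1 lower over the list alone, 1.47, 0.023, 0.481 estimated). TTN, a muscle gene, was the 1 gene called (495 against 6.74 CPM, 6.26 ± 0.74, edgeR adjusted p = 0.0251), with 630 at an unadjusted p under 0.05 and 185 calls by DESeq2, 33 with the block (19 higher, 14 lower) and 290 by limma voom with the block. The count of 1 became 0 without Regulatory_T replicate 1 or 2 or Effector_CD4pos_T replicate 1, 2, 3 or 4, and 3 without Regulatory_T replicate 3. The receptor list then lost its call without Regulatory_T replicate 1 (0.163) or Effector_CD4pos_T replicate 3 (0.0222) or 4 (0.0154), and mitosis without Regulatory_T replicate 3 (0.0539).

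Helper precursors were compared at rest. The mean log2 CPM of T cell markers ran from 1.96 to 8.15 in the Th2, 6.52 to 8.17 in the Th1 and 6.01 to 8.08 in the Th17 libraries. Th17 genes were higher in Th17 than in Th2 precursors (12 genes, 7 adjusted over the list alone, median 3.67, camera adjusted p = 1.75e-14), a call that held with an estimated correlation (0.0429). CCR6 was at 106 against 1.35 CPM, KLRB1 at 542 against 52.7, IL23R at 4.71 against 0.196 and the Th2 factor GATA3 at 112 against 156, and PTGDR2 was below the filter (0 against 0.0106). Th1 genes (9 genes, 2, 1.47, 1.14e-07, 0.15 estimated) and memory genes (23 genes, 1, 0.99, 4.72e-05, 0.15 estimated) were also higher in Th17 precursors, and Th2 genes did not pass (-0.64, 0.425). Between Th1 and Th17 precursors the Th17 list was lower in Th1 (13 genes, 1, -2.83, 2.62e-11, 0.0525 estimated), with CCR6 at 0.739 against 140.4 CPM, KLRB1 at 299 against 715, TBX21 at 0.601 against 1.73, CXCR3 at 17.7 against 4.79 and CCR4 at 14 against 12.6. Memory genes (-0.11, 0.0631) passed with the block (0.0327), and neither Th1 (0.01, test downward, 0.421) nor Th2 genes (0.45, 0.696) passed. Th1 against Th2 precursors gave higher Th1 genes (7 genes, 1, 1.14, 0.00227, 0.339 estimated), with CXCR3 at 12.7 against 0.488 CPM and IFNG at 20.4 against 2.44, and higher memory genes (0.94, 0.0252, 0.475 estimated, and 0.0621 with the block). GATA3 (145 against 152), CCR4 (10.3 against 14.6), TBX21 (0.431 against 0.0583) and PTGDR2 (0 against 0.0102) did not pass or were below the filter. Th2 genes had a median of 0.17, a mean of -0.07 and a downward test (0.828), and Th17 genes did not pass (0.66, 0.151). EdgeR called 0 genes in each of the 3 comparisons, with 618 (Th17 against Th2), 154 (Th1 against Th17) and 680 (Th1 against Th2) at an unadjusted p under 0.05 and 8, 5 and 148 calls by DESeq2. Without Th1 replicate 1, 1 gene passed between Th1 and Th17 precursors. In Th1 against Th2, the Th1 list lost its call without Th2 replicate 1 (unadjusted p = 0.0173) or both libraries of replicate 1 (0.0177) or 2 (0.0301). The memory list lost it without Th1 replicate 2 (0.277) or 3 (0.318) or Th2 replicate 1 (0.471), 2 (0.0256) or 7 (0.102).

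Myeloid dendritic cells were compared with monocytes at rest (3 and 4 libraries). Dendritic cell genes (11 genes, 8 adjusted over the list alone, median 4.7, camera adjusted p = 6.00e-11, 0.109 with an estimated correlation), MHC class II genes (11, 7, 2.25, 6.51e-05, 0.205 estimated) and plasmacytoid dendritic cell genes (9, 3, 2.96, 3.94e-04, 0.255 estimated) were higher. Monocyte markers were lower (13, 4, -3.19, 3.96e-08, 0.147 estimated). FCER1A was at 1769 against 27 CPM (edgeR adjusted p = 0.0878), CD1C at 1464 against 56.7, FLT3 at 54.1 against 3.29, CLEC10A at 146 against 27.8, CD14 at 13.7 against 923, VCAN at 197 against 2076 and S100A8 at 279 against 3461. Gene by gene, edgeR called 0 (879 at an unadjusted p under 0.05, 126 by DESeq2), and 12 or 9 without dendritic cell replicate 1 or 2.

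Interactions compared stimulation between a pair of cell types. Cytokines rose more in Memory_Teffs than in Naive_Teffs (18 genes, 7 adjusted over the list alone, median log2 difference of responses 5.95, camera adjusted p = 1.33e-29), and this held with an estimated correlation (7.34e-05). IL17A was at 69.6 CPM in stimulated memory cells, 0.133 in stimulated naive cells and 0 in both at rest, so the median can depend on the prior count. IFNG was at 994 and 6.58 CPM in memory cells with and without stimulation and at 4.35 and 0.171 in naive cells, IL2 at 831 and 3.86 against 576 and 0.262, and IL2RA at 1682 and 17.6 against 468 and 4.74. DNA replication (-1.08, 0.00447, 0.424 estimated) and mitosis genes (-1.05, 0.00343, 0.402 estimated) rose less in memory cells, and receptors did not differ past the threshold (0.03, 0.366). DNA replication lost its call without the libraries of replicate 2 (unadjusted p = 0.0169). EdgeR called 0 genes (638 at an unadjusted p under 0.05, 66 by DESeq2, 2 with the block, 14 by limma voom with the block) and 1 without treated Memory_Teffs replicate 3 or untreated Naive_Teffs replicate 3. Regulatory against effector CD4 (unequal IL-2 doses) gave a smaller rise of cytokines (-0.67, 0.00527, 0.274 estimated). Receptors (-0.09, 0.385) and regulatory T cell genes (0.52, 0.441) did not pass. FOXP3 (0.8), CTLA4 (-2.36), CD40LG (1.97) and IL2 (-1.19) did not pass by log2 difference of responses. Here edgeR called 0 genes (1252 at an unadjusted p under 0.05, 131 by DESeq2), and 5 without untreated Effector_CD4pos_T replicate 1. The cytokine list lost its call without treated Regulatory_T replicate 2 (0.0236) or untreated Effector_CD4pos_T replicate 1 (0.0367) or 7 (0.0156).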

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

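All tests of explanations in this part were chosen after the results were seen, while the outlier measures and interactions were planned.

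In groups of 4 libraries, a single library stood far from the other 3 in 7 of 128 tests, where chance gives 1 in 20. Total estimated counts were 16.51 M (mega counts) in treated effector CD4 T cells replicate 4 (31 to 33.3 in the others) and 7.34 M in untreated effector memory CD8 T cells replicate 3 (34.26 to 38.8). The mitochondrially encoded share was 8.13% in treated Mature_NK replicate 3 (3.77 to 4.41) and 8.21% in untreated Th17 precursors replicate 3 (3.21 to 3.59). The 10 most abundant genes held 26.01% of counts in treated central memory CD8 T cells replicate 3 (10.41 to 12.52) and 24.71% in untreated Th17 precursors replicate 3 (13.07 to 13.7). The correlation with GC content was 0.517 in untreated effector CD4 T cells replicate 1, against -0.216 to -0.111 in replicates of other donors.

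Stimulation responses differed between cell types in tests of the difference itself, given as the median log2 difference of responses. The lists in Memory_Teffs against Naive_Teffs were cytokines (5.95, 7.34e-05 by camera with an estimated correlation), Th2 genes (1.58, 0.0487 estimated), DNA replication (-1.08, 0.424 estimated), mitosis (-1.05, 0.402 estimated), MYC targets (-1.04, 0.307 estimated) and naive T cell genes (0.31, 0.316 estimated). In Regulatory_T against effector CD4 (unequal IL-2 doses, estimated p) they were cytokines (-0.67, 0.274), DNA replication (-3.42, 0.189) and mitosis (-2.96, 0.337). MYC targets (-1.37, 0.309), glycolysis (-0.95, 0.658), metallothioneins (-4.65, 0.274) and monocyte markers (3.28, 0.507) differed too. In groups left out of the comparisons, where treatment 2 used other donors, all libraries lay above all untreated libraries for activation receptors in Mature_NK (2.24) and Naive_Teffs under treatment 2 (2) and in Naive_Tregs under treatment 1 (2.62, 1 library against 2, with overlap under treatment 2 at 0.75), and for B cell activation in Naive_B under treatment 1 (1.9) and treatment 2 (1.31).

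Libraries of 1 group spread widely, over 149 libraries in 39 groups. Low depth is argued against by genes at 100 CPM or more, whose median log2 SD was 1.46. GC bias stays open, since the GC correction lowered the summed variance by 5.1% but raised that SD to 1.54. Deviations were shared between libraries of 1 donor (median correlation 0.28 after GC correction, -0.09 between donors), but biology and library preparation of a donor cannot be told apart, because each donor's libraries have no label for a batch.

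Interferon-stimulated genes were higher as a list under LPS for 6 h than for 24 h, with 0 of 23 passing alone and a camera adjusted p of 0.358 with an estimated correlation. The GC correction left their median at 2.86 against 2.99, which argues against GC bias as its cause. A baseline difference between the donor sets cannot be told apart from the treatment. Untreated libraries of 6 other cell types gave a mean of -0.37 for replicates 5 to 8 minus 1 to 4, against 3.48 in monocytes, but all of them came from replicate 7, which is 1 of the 4 donors. Dose, time and a donor-specific response to LPS stay open as well.

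Immediate early genes were lower as a list after stimulation of T cells, where 11 of 18 fell and 5 rose in the donor averages (0.305 estimated). GC bias is argued against by the median over all 18 members in the donor-averaged T cells, -3.37 after the correction against -3 before. An effect of the T cell beads alone is argued against by the other stimuli, since the list median was below 0 in 4 of 4 (Bulk_B -1.15, Mature_NK -2.91, monocytes -2.17, Mem_B -3.15). Time in culture stays open, because 0 untreated libraries carry a culture time, and handling of fresh cells could raise these genes at rest.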

How the results depend on the processing

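Alternatives added after the data were seen were the GC correction, limma voom, both with the block, the quality weights, leaving out libraries with low depth or an unmatched lineage, and the donor-averaged analyses with their alternatives. The others were planned. Values in parentheses after a count name the stimulation comparison, or one of these: memory Teffs, memory CD8 and memory B (against their naive counterparts at rest), resting and stimulated Tregs (Regulatory_T against effector CD4), Th1/Th2, Th17/Th2 and Th1/Th17 precursors, dendritic cells (against monocytes), the LPS protocols and both interactions. Counts not named moved by less than 1.5 times. For each result that moved or reversed, the cause was not tested.

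DESeq2 called more genes in all 30 comparisons: 1601 (Naive_Teffs), 1281 (Naive_CD8_T), 324 (Regulatory_T), 343 (Bulk_B), 196 (Mature_NK), 917 (monocytes), 374 (Mem_B), 1976 (CD8), 840 (central memory CD8), 1003 (effector memory CD8), 500 (gamma delta), 1281 (effector CD4), 1671 (follicular helper), 1117 (Memory_Teffs), 497 (Memory_Tregs), 1499 (Th1), 909 (Th17) and 2253 (Th2) after stimulation, and 78 (memory Teffs), 78 (memory CD8), 35 (memory B), 20 (resting Tregs), 185 (stimulated Tregs), 148 (Th1/Th2), 8 (Th17/Th2), 5 (Th1/Th17), 126 (dendritic cells), 1582 (LPS protocols), 66 (memory interaction) and 131 (Treg interaction) elsewhere. The directions of FCER2 in Bulk_B (-0.41), CCL2 in LPS protocols (-0.06) and IL2RA in memory interaction (0.01) reversed by log2 value, while 154 named genes kept their side of the threshold and 18 gained a call.

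With the replicate block the counts were 582 (Naive_Teffs), 41 (Regulatory_T), 9 (Bulk_B), 76 (Mem_B), 1007 (CD8), 159 (central memory CD8), 327 (effector memory CD8), 93 (gamma delta), 81 (effector CD4), 899 (follicular helper), 355 (Memory_Teffs), 120 (Memory_Tregs), 209 (Th1) and 196 (Th2), and 12 (memory Teffs), 33 (stimulated Tregs) and 2 (memory interaction). Reversed were PRF1 in Naive_CD8_T (0.51), MKI67 in Mature_NK (0.47), TNF in monocytes (-0.38), GZMB in memory CD8 (0.85), CD80 in memory B (1.57), GATA3 in Th1/Th2 (0.13), CCR4 in Th1/Th17 (-0.84), IL2RA in memory interaction (0.09), FOXP3 in Treg interaction (-3.02) and the Th2 genes list in Th1/Th17 (0.942), the last a p value. Among other named genes 144 kept their side of the threshold, 9 gained a call and 16 lost one, and among lists 93 kept it, 5 gained and 3 lost a call. A blocked fit of all groups together was not run.

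The block with GC correction gave 676 (Naive_Teffs), 377 (Naive_CD8_T), 62 (Regulatory_T), 7 (Bulk_B), 5 (Mem_B), 990 (CD8), 18 (central memory CD8), 186 (effector memory CD8), 102 (gamma delta), 49 (effector CD4), 286 (Memory_Teffs), 103 (Memory_Tregs), 102 (Th17) and 118 (Th2), and 15 (stimulated Tregs), with reversed values for MKI67 in Mature_NK (0.01), TNF in monocytes (-0.25), GZMB in memory CD8 (0.83), CD80 in memory B (2.13), GATA3 in Th1/Th2 (0.72), GATA3 in Th17/Th2 (0.06), CCR4 in Th1/Th17 (-0.86), IL2RA in memory interaction (0.21) and FOXP3 in Treg interaction (-3.21). Of other named genes 158 kept their side, 7 gained and 4 lost a call.

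Limma voom with the block gave 2094 (Naive_Teffs), 1134 (Naive_CD8_T), 23 (Regulatory_T), 49 (Bulk_B), 15 (Mature_NK), 760 (monocytes), 76 (Mem_B), 2435 (CD8), 286 (central memory CD8), 961 (effector memory CD8), 66 (gamma delta), 1181 (effector CD4), 2070 (follicular helper), 1288 (Memory_Teffs), 55 (Memory_Tregs), 717 (Th17) and 276 (Th2), and 115 (memory Teffs), 5 (resting Tregs), 290 (stimulated Tregs), 6 (Th1/Th17) and 14 (memory interaction). Reversed were PRF1 in Naive_CD8_T (0.28), MKI67 in Mature_NK (0.49), CD80 in memory B (1.12), GATA3 in Th1/Th2 (0.13), CCR4 in Th1/Th17 (-0.49) and FOXP3 in Treg interaction (-1.55), 20 named genes gained a call and 152 kept their side. Without the block limma voom gave 888 (Naive_Teffs), 652 (Naive_CD8_T), 13 (Regulatory_T), 4 (Bulk_B), 3 (Mature_NK), 10 (Mem_B), 916 (CD8), 67 (central memory CD8), 283 (effector memory CD8), 95 (gamma delta), 981 (effector CD4), 413 (Memory_Teffs), 30 (Memory_Tregs), 769 (Th1) and 249 (Th17), with 1 (memory Teffs) and 0 (stimulated Tregs), and IL6 in LPS protocols (1.83) reversed. In the LPS protocols, where no block can be fitted, 11 other named genes kept their side and 6 lost their call.

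Quality weights gave 1834 (Naive_Teffs), 1182 (Naive_CD8_T), 146 (Regulatory_T), 58 (Bulk_B), 3 (Mature_NK), 839 (monocytes), 419 (Mem_B), 1471 (CD8), 598 (effector memory CD8), 408 (gamma delta), 597 (effector CD4), 2081 (follicular helper), 1395 (Memory_Teffs), 115 (Memory_Tregs), 1159 (Th1), 1096 (Th17) and 1310 (Th2), and 3 (memory Teffs), 9 (memory CD8), 2 (memory B), 4 (stimulated Tregs), 134 (dendritic cells), 2719 (LPS protocols) and 2 (memory interaction). Quality weights with the block gave 4871 (Naive_Teffs), 4531 (Naive_CD8_T), 362 (Regulatory_T), 739 (Bulk_B), 103 (Mature_NK), 2875 (monocytes), 76 (Mem_B), 3289 (CD8), 252 (central memory CD8), 3089 (effector memory CD8), 668 (gamma delta), 1256 (effector CD4), 5267 (follicular helper), 4642 (Memory_Teffs), 414 (Memory_Tregs), 3047 (Th1), 3125 (Th17) and 3632 (Th2), and 342 (memory Teffs), 202 (memory CD8), 32 (memory B), 56 (resting Tregs), 441 (stimulated Tregs), 1 (Th1/Th2), 52 (Th17/Th2), 23 (Th1/Th17), 349 (dendritic cells) and 112 (memory interaction). Simulated data gave 0% (weights) and 3.6% (with block) false calls at a dispersion of 0.1, and 1 call each at the real one.

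GC correction alone gave 511 (Naive_Teffs), 571 (Naive_CD8_T), 4 (Regulatory_T), 1 (Bulk_B), 314 (monocytes), 324 (central memory CD8), 340 (effector memory CD8), 98 (gamma delta), 1193 (effector CD4), 96 (Memory_Tregs) and 1032 (Th2), and 7 (memory CD8), 6 (resting Tregs), 3 (stimulated Tregs), 9 (dendritic cells), 2 (averaged B cells) and 1 (averaged stimulated Tregs), with CCL2 in LPS protocols (-0.12) reversed. It moved the share of higher calls by over 10 points in Naive_Teffs, Naive_CD8_T, CD8, effector memory CD8, gamma delta, effector CD4, Mem_B and the averaged T cells. In the LPS protocols 14 other named genes kept their side and 3 lost their call.

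RLE size factors gave 69 (Mem_B), 32 (effector memory CD8) and 11 (gamma delta), and 5 (resting Tregs) and 107 (LPS protocols), with FCER2 in Bulk_B (-0.41), CCL2 in LPS protocols (-0.06) and IL2RA in memory interaction (0) reversed. All 193 other named genes and 106 lists kept their side, and 1 list lost its call. RLE moved the median log2 change of all genes by over 0.1 in Bulk_B (-0.21 to -0.44), effector memory CD8 (-0.03 to -0.25), gamma delta (-0.15 to -0.39), Th17 (-0.13 to -0.24), Th2 (-0.28 to -0.46), memory CD8 (-0.05 to 0.06), memory B (-0.01 to 0.25), resting Tregs (0.04 to -0.22), dendritic cells (-0.02 to 0.12), the Treg interaction (0.3 to 0.56), averaged B cells (0.26 to -0.04), averaged T cells (0.42 to 0.54) and averaged resting Tregs (0.19 to 0.06).

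Without a filter on low counts the counts were 44 (Regulatory_T), 109 (Bulk_B), 77 (Mem_B), 313 (central memory CD8), 91 (gamma delta), 36 (Memory_Tregs) and 242 (Th17), and 5 (stimulated Tregs), 154 (dendritic cells), 315 (LPS protocols), 1 (memory interaction), 52 (Treg interaction) and 2196 (averaged T cells), and CD80 in memory B (0.03) reversed. With the stricter filter of 5 CPM they were 5 (Bulk_B), 5 (Mem_B), 34 (gamma delta) and 14 (Memory_Tregs), and 8 (dendritic cells), 170 (LPS protocols), 1 (memory interaction), 1 (averaged B cells) and 2539 (averaged T cells), with GATA3 in Th1/Th2 (0.02) and IL2RA in memory interaction (0.12) reversed. No named gene still tested lost its call under either, and 6 and 1 gained one. Named genes that a filter removed have no value.

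One fit of all groups gave 25 (Regulatory_T), 139 (Bulk_B), 6 (Mature_NK), 116 (Mem_B), 105 (CD8), 176 (central memory CD8), 175 (effector memory CD8), 186 (gamma delta), 154 (follicular helper), 27 (Memory_Tregs), 143 (Th1), 103 (Th17) and 1121 (Th2), with PRF1 in Naive_CD8_T (0.01) reversed. It left 104 named genes on their side, ended 12 calls and added 1. Without libraries of low depth or unmatched lineage the counts were 3 (Bulk_B), 503 (effector CD4) and 85 (Memory_Teffs), and 19 (resting Tregs) and 0 (LPS protocols). List tests fell from 295 calls to 4 with an estimated correlation. A minimum change of 2-fold moved no count by 1.5 times, and 81 untreated libraries matched their lineage with either pseudocount.

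Leaving out 1 library or donor at a time gave counts of 3 to 310 (Naive_Teffs), 0 to 105 (Naive_CD8_T), 0 to 3 (Regulatory_T), 0 to 3 (Bulk_B), 0 to 1 (Mature_NK), 40 to 164 (monocytes), 2 to 46 (Mem_B), 114 to 529 (CD8), 55 to 129 (central memory CD8), 22 to 101 (effector memory CD8), 6 to 52 (gamma delta), 56 to 908 (effector CD4), 84 to 687 (follicular helper), 36 to 306 (Memory_Teffs), 0 to 70 (Memory_Tregs), 148 to 998 (Th1), 33 to 173 (Th17), 84 to 845 (Th2), 0 to 1 (memory CD8), 0 to 19 (resting Tregs), 0 to 3 (stimulated Tregs), 0 to 1 (Th1/Th17), 0 to 12 (dendritic cells), 0 to 77 (LPS protocols), 0 to 1 (memory interaction), 0 to 5 (Treg interaction), 1429 to 3785 (averaged T cells) and 247 to 315 (gene list tests). Counts stayed at 0 to 0 in memory Teffs, memory B, Th1/Th2, Th17/Th2, averaged B cells, averaged memory, averaged resting Tregs and averaged stimulated Tregs. Over all these fits 1135 values of named genes kept their side of the threshold, 425 lost and 4 gained a call, and for lists 1195 kept it, 58 lost and 40 gained a call. A left-out library lowers the number of samples, and the set of called genes was not compared. Genes whose direction reversed in some of these fits had log2 changes of MKI67 in Naive_CD8_T (-0.06 to 7.6), PRF1 in Naive_CD8_T (-1.04 to 1.3), IKZF2 in Regulatory_T (-0.02 to 1.2), FCER2 in Bulk_B (-0.12 to 2.62), GZMB in Mature_NK (-0.9 to 0.14), MKI67 in Mature_NK (-3.45 to 1.36), TNF in monocytes (-0.39 to 1.3), GZMB in memory CD8 (-2.02 to 0.41), TBX21 in memory CD8 (-0.45 to 3.07), CD80 in memory B (-1.66 to 1.82), CCR4 in Th1/Th2 (-1.92 to 0.29), GATA3 in Th1/Th2 (-0.32 to 0.51), GATA3 in Th17/Th2 (-0.73 to 0.1), CCR4 in Th1/Th17 (-1.28 to 0.58), CCL2 in LPS protocols (-0.13 to 1.54), IL1B in LPS protocols (-0.98 to 0.69), IL6 in LPS protocols (-1.32 to 2.84), TNF in LPS protocols (-0.38 to 1.51), IL2RA in memory interaction (-0.83 to 1.07), FOXP3 in Treg interaction (-2.23 to 1.35) and IL2 in Treg interaction (-10.04 to 1.09). None of them had passed. Lists that reversed had unadjusted p values of interferon-stimulated genes in Naive_CD8_T (0.573 to 0.961), mitosis in Regulatory_T (0.206 to 0.935), mitosis in Bulk_B (0.312 to 0.941), plasma cell markers in Bulk_B (0.24 to 0.949), T cell activation receptors in Mature_NK (0.157 to 0.967), MYC and ribosome biogenesis in Mature_NK (0.526 to 0.984), interferon-stimulated genes in Mature_NK (0.079 to 0.75), glycolysis in monocytes (0.16 to 0.888), NK cell markers in memory CD8 (0.0799 to 0.987), Th2 genes in Th1/Th2 (0.0965 to 0.919), Th1 genes in Th1/Th17 (0.023 to 0.682), Th2 genes in Th1/Th17 (0.19 to 0.84), memory and effector T cell genes in Th1/Th17 (2.27e-04 to 0.697) and NF-kB and inflammatory genes in LPS protocols (0.142 to 0.884).

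A gene at 0 in a library of 0.97 M counts can still reach several CPM. At the dispersion seen in Naive_Teffs edgeR recovered 2% of 16-fold changes, so the spread between libraries limits the calls there.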

Other observations

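NK cells under treatment 2 (2 libraries of replicates 6 and 7, so treatment and donors cannot be separated) carried more mitosis genes than untreated NK cells (mean log2 CPM higher by 3.22) and more DNA replication genes (2.45), and fewer cytotoxic granule genes (-2.72). Naive (1.12) and regulatory T cell genes (2.11) were higher and mitochondrially encoded genes lower (-0.52), and T cell markers ran up to 5.96 against 3.32 to 5.09. Naive B cells carried more IL-4 response genes under treatment 1 (3.89, 2 libraries) and, in other donors, under treatment 2 (2.58), while monocyte markers (-2.25 and -1.69) and B cell markers (-1.8 and -2.2) were lower.

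Other splits of the same libraries were tested for each count, chosen after the counts were seen. In the LPS protocols, without pairs, 1 of 35 splits (29 genes, highest other 7) cannot exclude chance over so many tests. The other comparisons between groups pair libraries by donor, and the splits that part as many pairs as the real one (8, or 12 in Mem_B) are too few for a share under 0.05. Of all 35 splits, 1 (the real one) gave as many genes in Naive_Teffs (317, highest other 0), Naive_CD8_T (143, 0), Regulatory_T (2, 0), CD8 T cells (545, 0), central memory CD8 (105, 10), effector memory CD8 (87, 0), gamma delta (22, 1), effector CD4 (324, 15), follicular helper (459, 0), Memory_Teffs (184, 0), Memory_Tregs (8, 0), Th1 (439, 0), Th17 (160, 116) and Th2 (586, 0). As many came from 2 of 35 splits in monocytes (193, and 249 for the split of replicates 1 and 2 from 3 and 4), 5 in Mem_B (36 and 69) and 2 in stimulated Regulatory_T against effector CD4 (1 and 353). A real count of 0 is reached by every split, so the count of splits (all 35) says nothing in Bulk_B (highest other 1), Mature_NK (246) and the rest comparisons of memory and naive Teffs (960), CD8 T cells (1552) and B cells (191), of regulatory and effector CD4 (453), of Th1 and Th2 (500), Th17 and Th2 (627) and Th1 and Th17 precursors (624), and of dendritic cells and monocytes (0). The same holds for all 50 drawn splits in the interactions of Memory_Teffs (457) and Regulatory_T (35). Splits calling up to 1552 genes where the real one called 0 point to a structure of the libraries, and that structure followed the donor. Among the splits that part as many pairs, none but the real one called over 10 genes, except in Mem_B (43), where 2 of the 12 gave as many. In monocytes and in stimulated Regulatory_T the real split was then alone, with 0 genes as the highest other. The splits that kept more donors together gave the 1552, 249 and 353 genes. The blocked counts are 269 in monocytes, 33 in stimulated Regulatory_T and 0 in effector memory against naive CD8 T cells. For averages over donors the sign patterns are too few for a share under 0.05: 1 of 8 in T cells (4310, highest other 0), 8 of 8 in memory against naive T cells and in stimulated regulatory T cells, and 4 of 4 in B cells and resting regulatory T cells (real 0 and highest other 0 in each).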
